A study of Escherichia coli str. K-12 substr. MG1655 with 10 samples.

How the data were processed

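The data were short-read RNA sequencing libraries of Escherichia coli K-12 MG1655. Per the labels' protocols, bacteria grew in M9 minimal medium and were harvested at an optical density of 0.4 to 0.6. Intracellular RNA came from pelleted cells by phenol-based extraction and was enriched for short RNA. Extracellular RNA came from filtered culture medium with a kit for RNA in serum. For the pull-downs, Dps was held on antibody beads, RNA was bound to it, washed, and eluted with salt. The titles of these 2 libraries name LB and M9, while the protocol text given for both names M9, so the media are used here as titles only. Libraries were made with an Ion Torrent total RNA kit, amplified, cut from a gel as short amplicons of 90 to 123 base pairs, and sequenced on an Ion Torrent PGM, per the labels' protocols. The gel step keeps short fragments, so reads from a long RNA are pieces of it.

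The deposited files held, per the file headers, a value at each coordinate of the genome for the top strand, the bottom strand and their sum. What the authors counted is not stated. The deposited values are read here as estimated counts of read 5′ ends, with reads that map to several places shared between these. That reading rests on the values, which peak at single bases at the start of tRNA genes and have fractional parts of shares. The header carried the numbers 12 and 50, read here as read lengths in bases, which the labels do not explain. The aligner, its settings and the genome build are not given in the sources used here. Each library covered positions 1 to 4641652, and 1 line without a coordinate in wild-type intracellular library 2 was left out. Files name no genes. Genes were taken from a table of the RefSeq assembly ASM584v2, whose gene positions were used to sum reads over genes and to name neighbours, and none of its coordinates is printed. On average over the libraries, 42.9% of reads began in a tRNA gene as placed, and 34.2% and 31.5% did when genes were shifted by 10 bases either way, so the table and the files were taken to share positions.

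The table gives no strand. A gene's strand was set to the one holding at least 80% of its reads, averaged over the 10 libraries as RPM, and otherwise both strands were summed, which gave 2761 and 1890 of 4651 genes. For the latter, sense and antisense reads were not separated. Copies, 141 genes in 31 families such as rRNA and tRNA genes, were summed to 1 item each, since their reads are shared. Expected counts per gene were rounded to whole numbers. A base in 2 genes of the same class and strand was left out, and elsewhere rRNA, tRNA and non-coding RNA genes took precedence over others. Totals per library ran from 6500 to 1019100 reads. Single positions held up to 18.7% of a library's reads, so counting intervals understate the error.

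Groups followed the titles, namely wild-type intracellular, wild-type extracellular, deletion intracellular and deletion extracellular with 2 libraries each, and 1 pull-down each for LB and M9. Replicate libraries differed by more than sampling noise, at 24.4 to 178.6 chi-square per degree of freedom, so none was a copy of another. The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM factors (0.437 to 2.344), filterByExpr, and a fit of all 8 libraries in 4 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 4466 items with a read, 2447 were tested. It gave 5 comparisons, namely extracellular against intracellular in each genotype, deletion against wild type in each fraction, and the interaction. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. DESeq2 1.42.0 was the other tool. Shares of RNA classes and the share of tRNA read starts nearer to the 5′ than to the 3′ end were compared by two-sided exact permutation tests. Pull-down ratios are CPM over the mean of the wild-type intracellular libraries, with exact Poisson intervals. Their lists were set against 10000 random lists matched in 20 bins of expression, by the median ratio and, added later, by the summed ratio. Ratios given with counting intervals in the other comparisons are of reads summed over a group and divided by summed effective library sizes, with exact binomial limits on the split of reads. Fold limits against a group at 0 use 3 reads over that group.

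The 21 lists, with 730 members, were small regulatory RNAs, housekeeping and CsrA-binding RNAs, type I toxin-antitoxin RNAs, leader peptides, RpoS, OxyR and SoxRS, Fur and iron, nucleoid protein, outer membrane, heat shock, SOS, flagella and chemotaxis, amino acid biosynthesis, glycolysis and TCA cycle genes, translation factors, RNA degradation genes, vesicle and secretion genes, cryptic prophage genes, ribosomal proteins, transfer RNAs and ribosomal RNA. The last has fewer than 5 members after merging and is given as a class. Named genes were chosen by a rule, with samples, tests and alternatives, before the data were examined. Per comparison, the rule takes the 12 largest rises and 12 largest falls with an adjusted p under 0.05, groups that do not overlap and a mean of at least 20 reads, or the 4 with the smallest p where none pass. It adds dps, up to 4 members with the smallest p per list described, and in the pull-downs the 12 highest ratios with at least 30 reads and the 6 lowest among genes with at least 100 reads in each reference library. From the lists, 1 to 4 of these members are given. Choices made after seeing data were the rRNA kinds, the Rac region and the windows set against it, the reads of list members that the filter left out, the tRNA start window, the set for opposite-strand reads, the scan of reads between genes and the count at 4-fold. A scanned interval needed at least 1000 RPM and 5 times the wild type.

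The alternatives were RLE and total-count scaling, DESeq2, no low-count filter, a replicate block, rRNA left out before scaling, both strands summed, base values capped at 10, each library left out, and the 2 compared groups alone. Shares were also taken outside rRNA genes, and tRNA starts over pooled reads and with at least 20 reads. Pull-downs were also set against deletion intracellular libraries, with rRNA left out and with at least 10 reads, and their correlation was repeated by Pearson, without rRNA and tRNA, and over genes with a mean of 30 reads. Lists were also tested with an estimated correlation and with members within 100 bases collapsed. Added later were copies tested separately, 5 bases upstream counted, each base counted at most once, and wild-type intracellular 1 with extracellular 2 left out. Scripts were tested on simulated data first, with 200 of 2447 genes changed. Between extracellular and intracellular RNA of the deletion, 52% of 100 genes changed 16-fold and 7% of 100 changed 4-fold were called, with 2 of 2247 unchanged genes. Between extracellular genotypes, 52% and 6% were called, with 0 of 2247 unchanged genes. A changed list of 30 genes had a camera adjusted p of 4.11e-20, and 0 of 100 unchanged lists were called. Simulated genes were drawn independently, so this could not test how camera performs on lists of correlated genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.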

Results

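Short RNA was sequenced from Escherichia coli K-12 MG1655 to ask how secretion of RNA differs with and without Dps, a DNA-binding and iron-storing protein of starved cells. RNA from inside cells and RNA from cell-free culture medium were sequenced in the wild type and in a strain with dps deleted, with 2 libraries in each of the 4 groups. A further 2 libraries, 1 titled LB and 1 titled M9 after growth media, held RNA bound by purified Dps on antibody beads. Libraries held 807438 and 1019100 reads (wild-type intracellular), 507487 and 526401 (wild-type extracellular), 773330 and 704818 (deletion intracellular), and 57397 and 144415 (deletion extracellular). The pull-downs held 9523 and 6500 reads. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Intervals and floors cover counting error only. Values below are means of normalised CPM ± SD with n = 2 unless stated.

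Reads on dps, the deleted gene, were examined first in every library. Wild-type intracellular libraries held 26.7 and 191 dps reads, and wild-type extracellular libraries 6.5 and 19. The deletion held 3 and 3 in intracellular and 1 and 1.1 in extracellular libraries. In wild-type intracellular library 2, 102 of the 191 reads began at 1 base. Between genotypes, dps was 16.6-fold lower in the deletion in intracellular RNA (95% counting interval 7.51 to 45.8), at a log2 fold change of -4.31 (SE 1.02) and an edgeR adjusted p of 0.178. With 1 library left out that log2 fold change ran from -5.20 to -1.65. In extracellular RNA dps was 3.11-fold lower in the deletion (0.775 to 27.1), with a log2 fold change of -1.54 (SE 1.38) and an edgeR adjusted p of 0.642. Between fractions of the wild type, dps was 3.14-fold lower outside cells (log2 fold change -2.01, SE 0.87, edgeR adjusted p 0.314). The log2 fold change of dps ran from -2.97 to 0.60 with 1 library left out, as it rests on wild-type intracellular library 2, with 240 CPM of dps against 20.4 in library 1 and 28.7 and 34.2 outside. Both pull-downs held 0 dps reads, which allows up to 315 RPM of all reads for LB and 462 RPM for M9.

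The first comparison set extracellular against intracellular RNA in the wild type. Intracellular RNA was extracted with phenol and enriched for short RNA, and extracellular RNA came from a kit for serum. Location and preparation thus cannot be told apart in any comparison of fractions. Among genes with the smallest p, rnpB, the RNA of ribonuclease P, stood at 923 ± 955 outside and 30.5 ± 4.74 inside cells, a ratio of summed reads of 20.8 (95% counting interval 16 to 27.5). Higher outside were also hybO and hycC, of hydrogenase complexes, at ratios of 52.7 (8.38 to 2190) and 21.3 (9.07 to 61.0). Lower outside were aroF, which opens aromatic amino acid synthesis, at 27.2 ± 15.6 against 1150 ± 1120, and ydiE, an iron-regulated gene, at 18.9 ± 6.39 against 308 ± 127. None of these passed the test, and for hybO, hycC and ydiE both strands were summed (70.4%, 54.6% and 68.6% on the majority strand). Their log2 fold changes were 4.91 (SE 0.97) for rnpB, 5.25 (SE 1.07) for hybO, 4.19 (SE 0.85) for hycC, -5.47 (SE 1.03) for aroF and -3.95 (SE 0.79) for ydiE, each at an edgeR adjusted p of 0.0671. The uncharacterised yiiX (6.03, SE 1.30), nrdF of ribonucleotide reductase (-3.49, SE 0.75) and trpC of tryptophan synthesis (-3.86, SE 0.86) had an edgeR adjusted p of 0.0722. By edgeR 0 genes were higher and 0 lower of 2447 tested, with 350 at an unadjusted p under 0.05, and DESeq2 called 16 higher and 35 lower. Leaving out 1 library gave 0 higher and 6 lower (without wild-type intracellular 2), 14 and 0 (without extracellular 1), or 33 and 1 (without extracellular 2).

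Lists of genes fixed before the data were examined were then tested against all other genes. Counts of members cover those that passed the low-count filter, which were 17 of 52 flagella genes, 10 of 31 prophage genes and 17 of 38 toxin-antitoxin RNAs, the lists that lost the most. Ribosomal protein genes were higher in wild-type extracellular RNA, with 48 of 54 positive and a median log2 fold change of 1.11 (limma camera adjusted p = 5.51e-08; adjusted p = 0.578 with an estimated correlation). Their members rplY and rpsF stood at 115 ± 12.9 against 23.7 ± 3.69 and 63.2 ± 14.9 against 11.2 ± 3.40. Heat shock genes were higher, with 17 of 21 positive and a median of 0.68 (camera adjusted p = 0.00134; adjusted p = 0.578 with an estimated correlation). Of these, ibpA, a small chaperone, stood at 84.7 ± 15.5 against 9.42 ± 2.65, and hslV, a protease subunit, at 80.6 ± 46.3 against 8.92 ± 0.194. Cryptic prophage genes were higher in 10 of 10 members at a median of 1.22 (camera adjusted p = 0.0222; adjusted p = 0.348 with an estimated correlation). The cold shock gene cspB of this list stood at 44.9 ± 23 against 6.78 ± 1.05. Transfer RNAs, 39 of 45 positive at a median of 0.92, were at a camera adjusted p = 0.00102 (adjusted p = 0.715 with an estimated correlation). Adjusted over the list alone, 3 heat shock genes and 1 prophage gene passed, against 0 of each list over all genes, and 0 ribosomal proteins and 0 transfer RNAs passed either way.

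Other lists were lower outside wild-type cells. Fur and iron homeostasis genes were lower in 38 of 47 members, at a median of -0.73 (camera adjusted p = 1.3e-05; adjusted p = 0.348 with an estimated correlation). The ribonucleotide reductase gene nrdE, read at 65.0 ± 23.2 against 557 ± 58.0, and fhuB of ferrichrome uptake, at 15.0 ± 5.90 against 66.4 ± 5.39, belonged to it. Type I toxin-antitoxin RNAs were lower in 14 of 17, at a median of -1.21 (camera adjusted p = 0.000872; adjusted p = 0.348 with an estimated correlation), with sibA at 149 ± 26.8 against 527 ± 12.5. Amino acid biosynthesis genes were lower in 62 of 85, at a median of -0.51 (camera adjusted p = 0.00367; adjusted p = 0.654 with an estimated correlation), with trpD of tryptophan synthesis at 51.2 ± 8.79 against 774 ± 704. Small regulatory RNAs were lower in 21 of 28, at a median of -0.86 (camera adjusted p = 0.00953; adjusted p = 0.578 with an estimated correlation), with arcZ at 105 ± 6.56 against 538 ± 354. Adjusted over the list alone, 2 Fur genes and 7 amino acid genes were lower, and 0 small regulatory and 0 toxin-antitoxin RNAs were. Of the 21 toxin-antitoxin members that the filter left out, 14 had reads, with 7 higher and 7 lower outside. The call of the amino acid list was lost with members within 100 bases collapsed.

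The remaining 12 lists did not pass in wild type. Their camera adjusted p values were 0.0524 for flagella and for translation factors, 0.0648 for nucleoid proteins and for glycolysis genes, 0.163 for OxyR and SoxRS genes and 0.274 for housekeeping RNAs. Vesicle genes stood at 0.532, outer membrane genes at 0.579, RNA degradation genes at 0.614, RpoS and SOS genes at 0.844 and leader peptides at 0.931. Leader peptides had a median of -0.01 and a mean of 0.37, and SOS genes a median of 0.14 and a mean of -0.06. Left-out libraries ended several calls by camera. Small regulatory RNAs reached an adjusted p of 0.147 without intracellular 2 and 0.204 without extracellular 1, and heat shock genes 0.0638 without intracellular 1 and 0.457 without extracellular 2. Without intracellular 1 the adjusted p of amino acid genes was 0.567 and that of prophage genes 0.115, which stood at 0.201 without extracellular 2 by camera. Transfer RNAs turned without intracellular 1 (camera adjusted p = 0.39) and without extracellular 1 (camera adjusted p = 0.00414). The median of all genes depended on scaling, at 0.05 with TMM and -0.74 with total counts in wild type, -0.44 and -0.03 in the deletion, -0.05 and -1.12 between intracellular genotypes, -0.51 and -0.32 between extracellular ones, and -0.46 and 0.71 for the interaction. Relative to that median each called list kept its direction under both scalings, as for transfer RNAs here, at 0.87 above it with TMM and 0.68 with total counts. The wild-type medians themselves were 0.92 with TMM and -0.06 with total counts for transfer RNAs, and 1.11 and 0.02 for ribosomal proteins. These lists thus stood higher outside relative to other genes, and not as a share of all gene reads.

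Extracellular RNA of the deletion was set against its intracellular RNA in the same way. Higher outside were gnd, of the pentose phosphate pathway, at 428 ± 153 against 51.3 ± 1.35, and fiu, an outer membrane receptor for iron-siderophores, at 144 ± 13.0 against 24.2 ± 12.1. The ratios of summed reads were 9.09 (95% counting interval 6.36 to 13.1; log2 fold change 3.07, SE 0.78) and 6.50 (3.59 to 11.9; log2 fold change 2.60, SE 0.71), with edgeR adjusted p of 0.0327 and 0.0398. Lower outside, with 0 extracellular reads, were smf, which aids DNA uptake in other bacteria, at least 13.8-fold at a floor of 3 reads over the group, and yrdB and yraN at least 10.7-fold and 9.53-fold. Also at 0 outside were ytfP (at least 9.07-fold lower), ydiE (7.83), yfeH (7.51), ygaM (7.18), thiS of thiamine synthesis (6.98), bioA of biotin synthesis (6.07), ilvX (5.29), the acid resistance regulator gadW (4.76) and recR of DNA repair (4.70). Their edgeR adjusted p ran from 0.0233 to 0.0415. For fiu, yrdB, ydiE and ygaM both strands were summed, with 74.9%, 65.9%, 68.6% and 65.2% of reads on the majority strand.

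In all, edgeR called 63 genes higher and 91 lower in deletion extracellular RNA, with 645 at an unadjusted p under 0.05. Total-count scaling called 47 and 11, and DESeq2 83 and 101. The 63 higher genes were 62 protein-coding genes and 1 pseudogene, and 2 of them, gnd and fiu, had a mean of 20 reads or more over the libraries. A gene with few intracellular reads can pass the low-count filter through the extracellular libraries, which favours positive values. The 91 lower ones were 70 protein-coding genes, 20 non-coding RNAs and 1 pseudogene, and 88 of them reached that mean. Intracellular reads were 0 for 16 of the higher genes and extracellular reads 0 for 22 of the lower ones. Over all 2447 tested genes, libraries of the 2 fractions did not overlap in 1439, where chance gives 33.3% for libraries alike in depth. The deletion's extracellular libraries were the smallest in the model, so genes with few reads can separate by depth alone. That excess is thus no measure of real differences. The other comparisons gave 1059 (fractions in wild type), 842 (intracellular genotypes) and 1045 (extracellular genotypes). Without any 1 of the 4 deletion libraries edgeR called 0 and 0. With each base counted at most once it called 3 and 3.

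Small regulatory RNAs fell in the deletion's extracellular RNA. Of 28 members 9 fell, 0 rose and 19 did not pass, and adjusted over the list alone 13 fell (median log2 fold change -2.71, or -1.98 with genes at 0 set to their bound; camera adjusted p = 0.000702; adjusted p = 0.432 with an estimated correlation). The RNA sdsR, made in stationary phase, was 19.3-fold lower outside (14.7 to 25.8), at 258 ± 79.0 against 5380 ± 16.5, and ryeA, encoded opposite it, was 23.2-fold lower (10.6 to 63.5). The envelope stress RNA rybB was 13.4-fold lower (7.02 to 29.5), and rydB at least 3.85-fold lower. Among type I toxin-antitoxin RNAs, made up of toxin genes and the antitoxin RNAs that keep their peptides from being made, 6 of 17 fell and 1, hokA, rose. Adjusted over the list alone 12 fell and 1 rose (median -3.05, or -2.70 with genes at their bound; camera adjusted p = 0.000143; adjusted p = 0.148 with an estimated correlation). The antitoxins rdlA, rdlB and rdlC were 57.2-fold (37.4 to 92.5), 57.8-fold (37.8 to 93.4) and 56.6-fold (34.8 to 99.2) lower, though near-identical copies share reads and their split is uncertain. The antitoxin sibB was 18.5-fold lower (10.8 to 34.8), at 68.1 ± 1.07 against 1230 ± 295. Of the 21 toxin-antitoxin members that the filter left out, 11 had reads, 22 outside and 13 inside. Among these, 9 were higher and 2 lower outside, a count made after the data were seen.

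Fur and iron homeostasis genes fell as well, with 9 of 47 lower and 1, fiu, higher, and 14 lower and 1 higher adjusted over the list alone. Their median was -1.79, or -1.37 with genes at their bound (camera adjusted p = 0.00267; adjusted p = 0.465 with an estimated correlation; 0.133 without deletion extracellular 2). The iron regulator fur was 15.3-fold lower outside (5.18 to 74.9), feoC of ferrous iron uptake 28.5-fold (11.1 to 105), exbD of siderophore uptake 19.7-fold (7.63 to 72.6) and nrdE 11.4-fold (5.46 to 28.4). Amino acid biosynthesis genes had 4 of 85 lower and 10 adjusted over the list alone, at a median of -1.14 (camera adjusted p = 0.044; adjusted p = 0.975 with an estimated correlation). Among them trpC was 24.6-fold lower (6.73 to 204), trpA 15.7-fold (8.75 to 31.6), ilvG of branched-chain synthesis 11.3-fold (7.12 to 19.2) and gltD of glutamate synthesis 7.13-fold (3.83 to 15.0). The call of this amino acid list fell short with the replicate block. That list call was lost without deletion intracellular 1 (camera adjusted p 0.157), without extracellular 1 (0.0843), with neighbouring genes collapsed (0.336) and with total counts (0.053).

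Genes of cryptic prophages rose in the deletion's extracellular RNA. Of 10 members tested, with 21 left out by the filter, 2, the integrase genes intR and intE, rose over all genes and 3 adjusted over the list alone, 9 were positive, and the median was 2.31 (camera adjusted p = 0.000702; adjusted p = 0.148 with an estimated correlation). Of the 21 left out, 17 had reads, 31 outside and 40 inside, and 12 were higher and 5 lower outside, a count made after the data were seen. Reads of intR, of the Rac prophage, stood at 172 ± 5.38 outside against 6.78 ± 4.66 inside, a ratio of 28.1 (11.6 to 82.0). The intE value, of the e14 prophage, was 57.4 ± 81.2 against 2.61 ± 3.70, a ratio of 25.5 (7.22 to 138) over 3 intracellular reads, and its log2 fold change of 4.39 turned to -3.84 without extracellular 2. Ribosomal protein genes were 38 of 54 positive at a median of 0.65 (camera adjusted p = 0.00371; adjusted p = 0.975 with an estimated correlation; 0.0786 without intracellular 2 and 0.43 without extracellular 2). The member past the threshold, rplQ, was 10.7-fold lower outside (6.43 to 19.1), but its log2 fold change turned to 0.51 with each base counted at most once. Adjusted over the list alone 0 ribosomal proteins passed. The 14 other lists had camera adjusted p of 0.17 to 0.965, among them transfer RNAs at 0.801 with 35 of 45 lower. SOS genes and vesicle genes had medians of -0.35 and -0.48 with a test direction above other genes (camera adjusted p 0.954 and 0.801).

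Calls shared by the genotypes were counted next. With 0 calls in wild type, 0 were shared by edgeR, while DESeq2 shared 7 higher and 17 lower. Of the 63 genes higher in the deletion, 60 were positive in wild type and 35 had an unadjusted p under 0.05 there. Of the 91 lower genes 90 were negative and 44 had an unadjusted p under 0.05. Over all genes the sign was shared by 66.8% and the Pearson correlation of log2 fold changes was 0.53, across genes that are not independent replicates. The comparisons share no library.

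Intracellular RNA of the deletion was then set against that of the wild type. The flagella and chemotaxis list was higher in the deletion by camera with its preset correlation (adjusted p = 6.7e-28), and not with an estimated one (camera adjusted p = 0.115). The chemoreceptor genes tar and tap stood at 59.4 ± 5.09 against 0.755 ± 1.07 and 60.6 ± 6.87 against 1.38 ± 0.180, flgK, for a protein at the junction of hook and filament, at 50.4 ± 7.14 against 0.755 ± 1.07, and fliA, the sigma factor of flagella, at 45 ± 10.3 against 0.377 ± 0.534. The motor gene motB also rose, at 41.3 ± 15.6 against 0.377 ± 0.534. For tap, fliA and motB both strands were summed, with 61.4%, 74.3% and 73.3% of reads on the majority strand. Of the 17 members tested, 5 rose and 12 did not pass, 13 rose adjusted over the list alone, and 17 were positive at a median log2 fold change of 3.11. The test with the preset correlation kept its side without each of the 8 libraries in turn, at 3.11e-36 to 7.92e-17. The filter left out 35 of the 52 fixed members, and a gene with few wild-type reads passes it through the deletion libraries, which favours positive values. Of the 35, 34 had reads in these groups, 350 in the deletion and 73 in the wild type, and 32 were higher in the deletion, a count made after the data were seen.

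**Figure D1:**
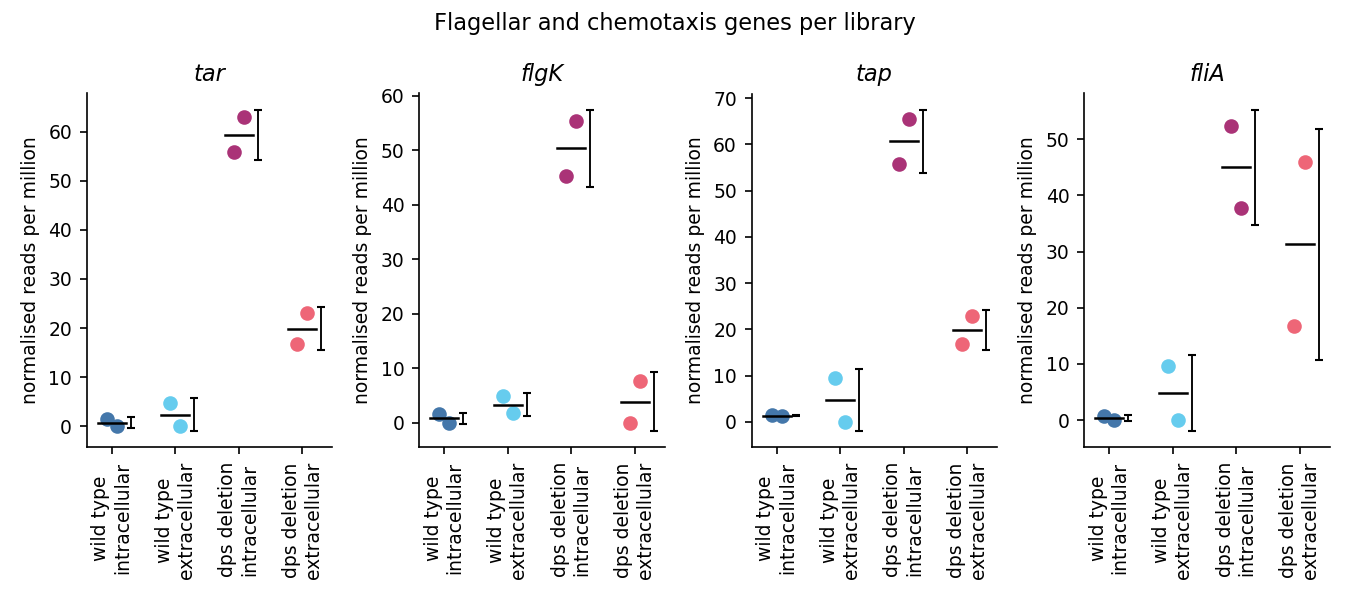
Normalised CPM (y axis) of tar, flgK, tap and fliA in each library of the 4 groups (x axis); points are libraries, lines means and bars SD (n = 2). In intracellular RNA the mean of tar was 59.4 in the deletion and 0.755 in the wild type. Both strands were summed for tap and fliA.

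In all, edgeR called 7 genes higher and 0 lower between intracellular genotypes, with 101 at an unadjusted p under 0.05, and DESeq2 called 6 and 1. Each had a mean under 20 reads, outside the rule for named genes, and is named after its values were seen. The ratios of summed reads were 62.3 for tar (16.5 to 527), 52.5 for flgK (13.8 to 446), 42.3 for tap (13.8 to 211), 98.4 for fliA (16.8 to 3970) and 91.8 for motB (15.6 to 3710). The others were rdcB, at 153 (26.6 to 6130), and uhpU, a small RNA, at 22.8 (10.5 to 58.7). Their edgeR adjusted p lay between 0.0229 and 0.0359. The count became 0 higher and 2 lower without wild-type intracellular 1, 0 and 3 without wild-type intracellular 2, and 1 and 0 without deletion intracellular 1, with 0 of the 7 kept. Without deletion intracellular 2 it was 3 and 0 with 1 kept, without either deletion extracellular library 0 and 0, and with total-count scaling 0 and 1.

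Transfer RNAs were higher inside the deletion in 44 of 45 families, at a median of 0.97 (camera adjusted p = 1.47e-15; adjusted p = 0.741 with an estimated correlation; 0.0942 without wild-type intracellular 1). That library stood apart, with 22.8% of its reads in transfer RNA against 44.5% to 54.6% in the other intracellular libraries, and a TMM factor of 2.34. Of its tRNA starts, 12% lay in the last 20 bases of the gene, against 0.416% to 0.863%. The aspartate family aspTUV stood at 66900 ± 14900 against 17200 ± 13800 CPM. Housekeeping and CsrA-binding RNAs were higher in 6 of 6, at a median of 0.90 (camera adjusted p = 0.000122; adjusted p = 0.625 with an estimated correlation; 0.0946 without wild-type intracellular 1). Of these rnpB stood at 172 ± 44.4 against 30.5 ± 4.74 and ssrA, which rescues stalled ribosomes, at 8190 ± 680 against 3120 ± 1880. Toxin-antitoxin RNAs were higher in 14 of 17, at a median of 0.51, or -0.41 with total counts, against medians of all genes of -0.05 and -1.12 (camera adjusted p = 0.000917; adjusted p = 0.212 with an estimated correlation; 0.065 without wild-type intracellular 1). The toxin gene hokD stood at 50.2 ± 10.4 against 5.27 ± 3.19 and the antitoxin RNA sokC at 3340 ± 77.5 against 1080 ± 874. In these 3 lists 0 members passed over all genes, and 1 toxin-antitoxin RNA did adjusted over the list alone. Of the 21 toxin-antitoxin members that the filter left out, 11 had reads, with 4 higher and 7 lower in the deletion. Lower but not past the threshold were aroF (-3.42, SE 0.90, edgeR adjusted p 0.255), ilvB (-2.46, SE 0.68, adjusted p 0.315) and zinT (-6.08, SE 1.73, adjusted p 0.369). The zinT value rests on 1 library, with 1 and 137 zinT reads in the wild type and 1 and 0 in the deletion, and ran from -8.44 to 0.33 with 1 library left out. The 16 other lists had camera adjusted p of 0.108 to 0.998. Median, mean and test did not share a sign for OxyR genes (median 0.07), nucleoid proteins (0.16), outer membrane genes (-0.09), heat shock genes (-0.06), glycolysis genes (-0.07), translation factors (-0.12) and prophage genes (0.16).

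Extracellular RNA was compared between the genotypes to ask which RNAs outside cells differ without Dps. Flagella genes were higher in the deletion in 17 of 17 tested of 52 fixed, at a median of 1.76 (camera adjusted p = 9.32e-06; adjusted p = 0.572 with an estimated correlation), with 0 members past the threshold either over all genes or adjusted over the list alone. Of the 35 left out by the filter, 24 were higher and 10 lower, over 51 and 77 reads. The flagellin gene fliC stood at 121 ± 99.5 against 36.8 ± 11.5. Heat shock genes were lower in 19 of 21, at a median of -1.68 (camera adjusted p = 0.00309; adjusted p = 0.572 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. The chaperone gene htpG stood at 7.65 ± 10.8 against 172 ± 101, and hslV had 0 deletion reads, at least 6.05-fold lower. Prophage genes were higher in 8 of 10, at a median of 1.04 (camera adjusted p = 0.00549; adjusted p = 0.5 with an estimated correlation), with 1 higher adjusted over the list alone and 0 over all genes. Here intR stood at 172 ± 5.38 against 18.3 ± 8.01. The prophage call was lost without wild-type extracellular 1 (camera adjusted p 0.089) and deletion extracellular 2 (0.0653), while the flagella and heat shock calls held without each library.

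Among single genes edgeR called 1 higher and 0 lower between extracellular genotypes, with 322 at an unadjusted p under 0.05, and DESeq2 called 4 and 6. The gene was dgoA, of galactonate breakdown, with 6 and 59 reads in the deletion and 0 in the wild type, at least 87.2-fold higher (edgeR adjusted p 0.0158). It is named after its value was seen, since its mean was under 20 reads. Without wild-type extracellular 1, wild-type extracellular 2 or deletion extracellular 2 edgeR called 0 and 0, and without deletion extracellular 1 it called 1 and 0, with 0 kept. Lower without passing were hslV, htpG (log2 fold change -4.08, SE 1.06), sibB (-3.28, SE 0.85) and glpF of glycerol uptake, which had 0 deletion reads and was at least 4.47-fold lower, each at an edgeR adjusted p of 0.292. The 17 other lists had camera adjusted p of 0.0731 to 0.924. OxyR, SOS and transfer RNA lists had medians of -0.51, -0.63 and -0.87 with a test direction above other genes. Between the genotype comparisons 0 calls were shared, where 0.003 were expected by chance in the higher direction, and 51.7% of genes shared their sign (Pearson correlation 0.05 across genes).

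The Rac prophage was read more densely in the deletion's extracellular RNA, a region chosen after the data were seen. Positions with a whole-number read start were 4.31 and 4.71 times as dense in the prophage as in the rest of the genome there. The ratio was 0.873 and 0.412 in wild-type extracellular, 0.351 and 0.408 in wild-type intracellular and 0.496 and 0.530 in deletion intracellular libraries. Of 199 windows of the same length elsewhere in the genome, 0 reached the prophage's ratio in library 1 and 1 did in library 2, at 8.07, with 0 in both. Single windows also reached 3.89 to 8.05 in the other 6 libraries.

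**Figure D2:**
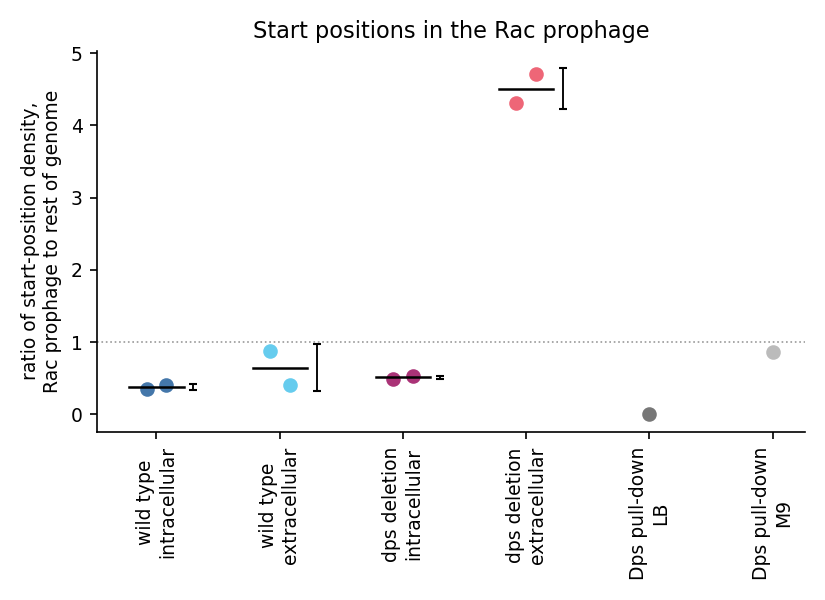
Density of read start positions in the Rac prophage divided by that in the rest of the genome (y axis) for each library, by group (x axis); the dotted line marks 1, lines are means and bars SD (n = 2). Both deletion extracellular libraries, at 4.31 and 4.71, lie above the other libraries.

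The interaction asked whether the difference between fractions differed between genotypes. Genes of the cryptic prophage list had higher values outside relative to inside in the deletion than in the wild type, in 8 of 10 members at a median of 1.11 (camera adjusted p = 0.0111; adjusted p = 0.348 with an estimated correlation). Toxin-antitoxin RNAs had a negative interaction value in 15 of 17, at a median of -1.98 (camera adjusted p = 0.00676; adjusted p = 0.348 with an estimated correlation), with rdlA at -4.31 and sibB at -3.93. Heat shock genes, which were higher outside wild-type cells, had a negative interaction value in 17 of 21, at a median of -1.69 (camera adjusted p = 0.00676; adjusted p = 0.822 with an estimated correlation), and small regulatory RNAs had one in 24 of 28, at -1.62 (camera adjusted p = 0.0111; adjusted p = 0.757 with an estimated correlation). Transfer RNAs had a negative value in 44 of 45, at -1.88 (camera adjusted p = 0.0111; adjusted p = 0.854 with an estimated correlation). With TMM they were higher outside wild-type cells in 39 of 45 and lower outside the deletion in 35 of 45. Adjusted over the list alone 1 toxin-antitoxin RNA passed and 0 members of the other 4 lists, against 0 over all genes. The toxin-antitoxin and prophage values cover the 17 of 38 and 10 of 31 members that passed the filter. By edgeR 0 genes passed, with 222 at an unadjusted p under 0.05 and 0 by DESeq2, and the smallest adjusted p was 0.52, for genes such as kilS (7.58), aroF (4.69), csrA (-4.05) and hslV (-8.62).

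Several of these list calls rested on 1 library. Without deletion extracellular 2 the camera adjusted p was 0.0796 for small regulatory RNAs and for prophage genes, 0.0666 for toxin-antitoxin RNAs and 0.233 for transfer RNAs. Prophage genes stood at 0.123 without wild-type extracellular 1, and transfer RNAs at 0.535 without wild-type intracellular 1 and, in the other direction, at 0.467 without wild-type extracellular 1. Without wild-type intracellular 2, edgeR called 1 gene lower. The 15 other lists had camera adjusted p of 0.0589 to 0.945, and OxyR, SOS and vesicle genes had medians of -0.54, -0.46 and -0.66 with a test direction above other genes.

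Ribosomal RNA was a larger part of extracellular than of intracellular reads. It made up 30.1% ± 12.8 (SD, n = 4) of extracellular and 9.30% ± 2.51 (n = 4) of intracellular reads (exact permutation p = 0.0286, the smallest for 4 against 4; 0.172 adjusted over 6 classes). In wild type the shares were 20.1% ± 8.45 and 9.42% ± 3.63, and in the deletion 40.1% ± 3.87 and 9.18% ± 2.37 (exact p = 0.33 each, the smallest for 2 against 2). Transfer RNA took 41.7% ± 16.8 outside and 43% ± 14.1 inside (exact p = 0.914), and other non-coding RNA 7.54% ± 11.2 and 14.4% ± 2.66 (exact p = 0.314). For protein-coding, antisense and intergenic reads exact p was 0.571, 0.657 and 0.143. In the deletion other non-coding RNA was 1.56% ± 0.299 outside and 12.8% ± 1.19 inside (exact p = 0.33). Enrichment for short RNA is named for intracellular RNA only. Location and preparation therefore cannot be told apart for these classes or for the kinds of rRNA below.

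The kinds of rRNA were separated after the data were seen. As percent of gene reads, 16S rRNA took 13.3 ± 6.76 outside and 1.02 ± 0.246 inside, and 23S rRNA 16.2 ± 4.79 and 2.53 ± 0.719 (n = 4; exact permutation p = 0.0286 each, adjusted 0.0358 over 5 tests). The short 5S rRNA went the other way, at 3.61 ± 0.754 and 8.29 ± 3.56 (exact p = 0.0286, adjusted 0.0358), and turned to 0.521 points higher outside with base values capped at 10. The other 2 of the 5 tests were 16S and 23S together (exact p = 0.0286) and the non-coding RNA fimR2 (exact p = 0.743). This family was put together after the data were seen, and the adjusted values depend on it. The planned exact test of all rRNA, at the same p of 0.0286, had 0.172 adjusted over 6 classes. The deletion's extracellular libraries held 18.8% 16S and 20.3% 23S on average, and the wild type's 7.78% and 12.2%.

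**Figure D3:**
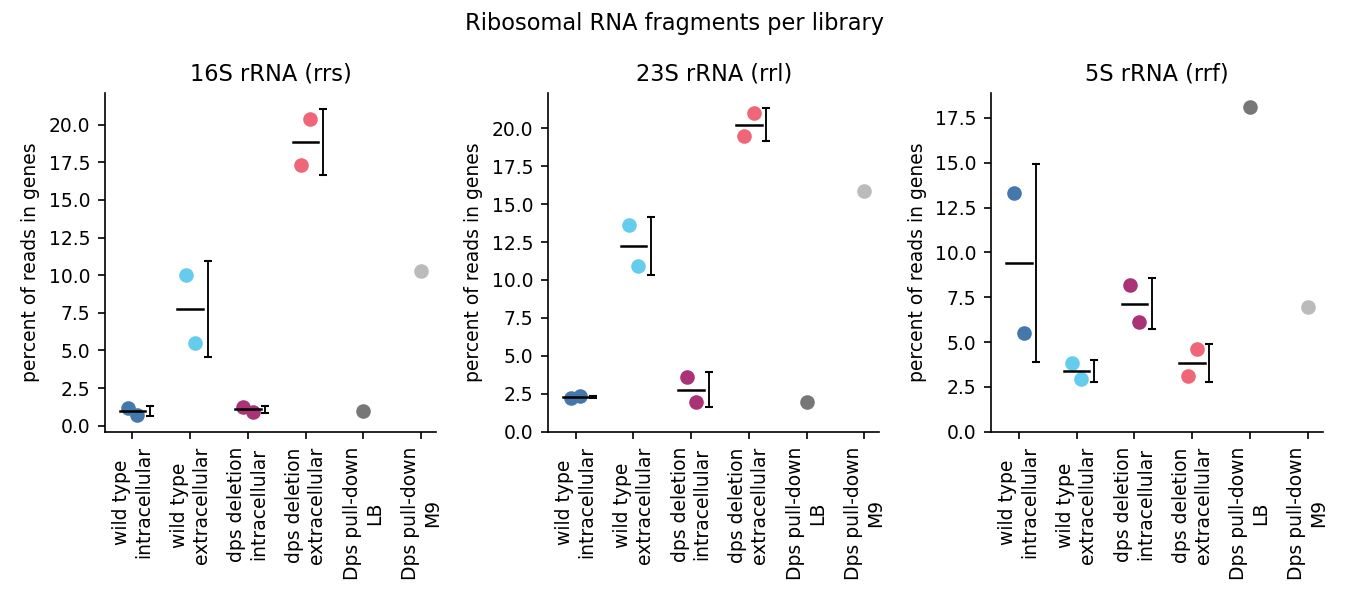
Percent of gene reads in 16S, 23S and 5S rRNA (y axis) for each library in the 6 groups (x axis); points are libraries, lines means and bars SD where n = 2. Extracellular libraries average 13.3% 16S rRNA, and intracellular ones 1.02%.

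Transfer RNA reads began mostly in the 5′ part of the gene in both fractions. Over 39 families with at least 50 reads in each library, 68.3% ± 11.5 of read starts lay nearer to the 5′ end of the gene than to its 3′ end outside cells and 66.2% ± 7.55 inside (n = 4, exact permutation p = 0.714). The first base alone held 35.8% and 71.0% of tRNA starts in wild-type intracellular libraries, 78.5% and 66.9% in wild-type extracellular, 71.1% and 61.0% in deletion intracellular, and 30% and 66% in deletion extracellular libraries. In deletion extracellular library 1, 38.4% of starts lay at bases 44 to 50, a window chosen after the data were seen, against 5.01% to 10.7% in the other 7.

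**Figure D4:**
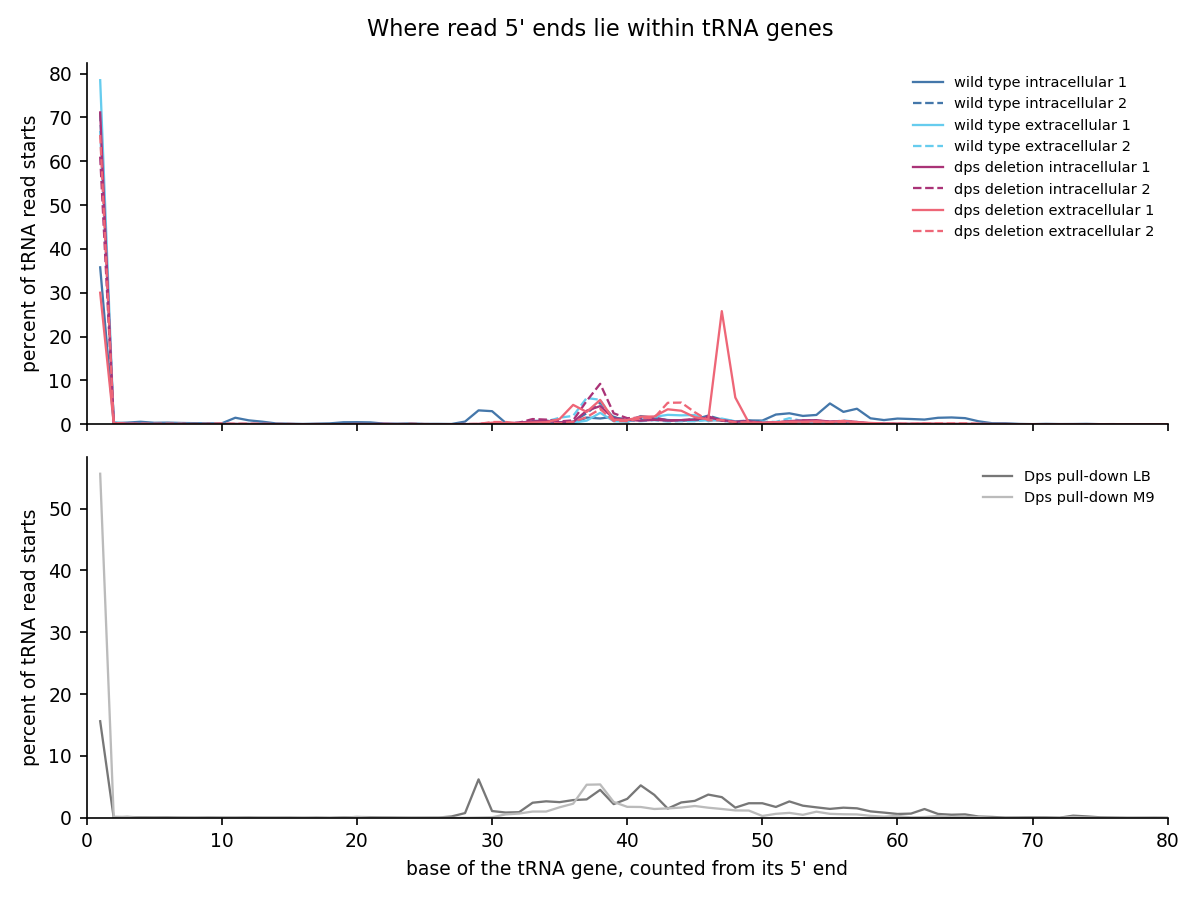
Percent of tRNA read starts (y axis) by base of the tRNA gene (x axis), for the 8 libraries at the top and the 2 pull-downs at the bottom. The first base holds 30% to 78.5% of starts in the 8 libraries, and deletion extracellular library 1 has a further peak near base 47.

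RNA bound by Dps was described against wild-type intracellular RNA without a test, since each pull-down was 1 library with no replicate. The reference libraries grew in M9, per the protocols. If the title LB names the medium of the bound RNA, medium and binding by Dps cannot be told apart in any LB ratio below. No library held RNA from beads without Dps, or the RNA before binding. The reference RNA was also prepared in another way. Binding by Dps, binding to beads and preparation therefore cannot be told apart in the ratios of either pull-down. In the pull-down titled LB, the arginine tRNA argW stood at a ratio of 8.45 (95% Poisson interval 5.85 to 11.8), serT at 5.78 (4.93 to 6.73) and proM at 4.09, followed by the antitoxin RNA sokC (3.85), gltTUVW (3.85), glnUW (3.83), leuU (3.18) and thrU (3.04). The next were asnTUVW (2.82), glnVX (2.73), the lipoprotein gene lpp (2.71) and valTUXYZ (2.38). To wild-type intracellular 1 and 2 alone, the ratios were 1.49 and 14.7 for lpp and 2.06 and 4.47 for asnTUVW. The iron-regulated RNA ryhB and sdsR had 0 reads, at least 24.2-fold and 22.3-fold under the reference at a floor of 3 reads, as did spf (8.81), aroF (6.92), micA (5.42) and trpD (4.58). The limits of aroF and trpD rest on wild-type intracellular 1, with 2575 and 1686 reads against 291 and 220 in library 2. In the pull-down titled M9, csrB, which binds the regulator CsrA, stood at 9.05 (6.68 to 12) and rprA, which activates RpoS, at 5.69 (4.02 to 7.80). The reference libraries held 125 and 1692 rprA reads, and its ratio to each alone was 30.1 and 3.14, against 9.46 and 8.68 for csrB. In LB these were 13.1 and 6.24 for argW and 12.7 and 3.75 for serT. Ratios of 16S and 23S rRNA were 10.7 and 6.93 in M9 and 0.989 and 0.859 in LB, and 5S stood at 0.736 and 1.92. After these came metVWYZ (2.24), leuU (1.89), valW (1.44), alaWX (1.29), aspTUV (1.28), serV (1.20), glyVWXY (1.18), alaTUV (1.08), tyrTUV (1.01) and thrU (0.962). Against wild-type intracellular 1 alone, alaWX, serV, glyVWXY, alaTUV, tyrTUV and thrU stood at 2.24, 4.03, 2.32, 1.82, 3.26 and 1.82. Against library 2 alone they lay below 1, at 0.91, 0.706, 0.788, 0.768, 0.598 and 0.653, while metVWYZ, leuU, valW and aspTUV stayed above 1 against each. With 0 reads in M9, aroF was at least 4.68-fold, lpp 3.25-fold, trpD 3.10-fold, leuB 2.39-fold, tyrA 2.31-fold and rsd 2.22-fold under the reference. For aroF, lpp, trpD, tyrA and rsd these limits rest on wild-type intracellular 1. That library held 2575, 1752, 1686, 1205 and 1125 of their reads, against 291, 252, 220, 232 and 272 in library 2.

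The tRNA list had a median ratio of 1.36 in LB, at percentile 100 of 10000 random lists of the same size and expression, and 0.844 in M9, at percentile 99.9. Of its 45 members, 44 and 43 had pull-down reads. Most tested genes had none, which holds down the medians of random lists, at 0.334 and 0.452 in the middle. A high percentile by the median is thus no sign of enrichment, and even a ratio below 1 reached 99.9. Housekeeping RNAs lay at medians of 0.597 (percentile 72.2) and 1.11 (97.2). Small regulatory RNAs had summed ratios of 0.244 (0.190 to 0.308) and 0.452 (0.363 to 0.557), with medians at the floor of 0. In LB the summed ratio was lower for amino acid biosynthesis (0.0696), Fur (0.0744) and OxyR genes (0.106), and leader peptides had 0 reads. In M9 the summed ratios of these lists were 0.418, 0.449, 0.261 and, over 3 reads, 0.477. Their medians were 0, as were those of random lists, so summed ratios were set against random lists after the data were seen. In LB the percentiles were 2.29 for small regulatory RNAs, 0.06 for amino acid, 1.26 for Fur and 3.05 for OxyR genes, and 2.44 for leader peptides. In M9 they were 10.1, 8.05, 9.79, 4.59 and 27.2. The summed ratios of the tRNA list, 1.42 and 0.849, lay at percentiles 80.3 and 50.2, below those of its medians, and those of housekeeping RNAs, 1.59 and 1.30, at 74.4 and 88.3. Of genes with at least 30 reads, 3 of 41 in LB and 4 of 28 in M9 reached 4 times the reference, a count chosen after the data were seen. Without wild-type intracellular 2 these were 11 and 6, and without wild-type intracellular 1 they were 4 and 3.

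Enrichment in the pull-downs was finally set against the extracellular difference between genotypes, over 2447 genes that are not independent replicates. Spearman's rho was 0.599 for LB and 0.625 for M9, while permuting genes within expression deciles gave a mean of 0.607 and 0.605 (permutation p = 0.215 and 0.0044). Of the 2447 genes, 605 in LB and 677 in M9 had a pull-down read. Over genes with a mean of at least 30 reads rho was 0.249 and 0.244 (permutation p = 0.847 and 0.491). By Pearson the values were 0.631 and 0.652 (permutation p = 0.0001, the smallest these permutations can give). With rRNA and tRNA left out rho was 0.594 and 0.618 (permutation p = 0.0858 and 0.0124).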

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

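The tests of the prophage reads below were all chosen after the result was seen, while the lists and their test were fixed earlier. In 5 lists the difference between fractions was not the same in the 2 genotypes, by limma camera on the interaction. Toxin-antitoxin RNAs and heat shock genes had an adjusted p of 0.00676, and small regulatory RNAs, prophage genes and transfer RNAs one of 0.0111. With an estimated correlation these were 0.348, 0.822, 0.757, 0.348 and 0.854. Heat shock genes kept their side of the threshold without each library in turn, and the other 4 lists did not.

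Single intervals between genes, whose reads were compared only as a share of all reads, held a further signal. On the bottom strand between kilS and sieB in the Rac prophage, the deletion's extracellular libraries averaged 3630 RPM, from 4410 and 2850. The wild-type extracellular libraries held 215 and 43.7, and intracellular libraries of both genotypes 9.91 to 144.

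Both deletion extracellular libraries read the Rac prophage densely, at density ratios of 4.31 and 4.71, and 1 technical explanation was weighed. DNA of the prophage itself, as a freed circle, could be read instead of its RNA and would fall on both strands alike. The lesser strand held 37.8% and 42.4% of the prophage's positions, within the 35.9% to 47.1% of intracellular libraries. This count cannot tell DNA and RNA of the prophage apart, which stays open. It weighs each position alike, so the number of reads between kilS and sieB on the bottom strand does not enter it. A difference due to the deletion also stays open, untested beyond the 2 libraries.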

How the results depend on the processing

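The alternatives chosen only after the results were seen were the joint omission of wild-type intracellular library 1 and wild-type extracellular library 2, each base counted at most once, 5 bases added upstream of genes, copies tested separately, the left-out libraries for the gene lists and the pull-downs, every setting for the rRNA kinds and for the overlap of calls, and the correlation over genes with at least 10 pull-down reads. Leaving out 1 of 2 libraries makes the model assume that the lone library varies like the other groups. Among named genes, 1582 values under the other settings kept their direction and side of the threshold, 76 newly passed it, 106 no longer passed and 8 turned. With 1 library left out, the corresponding numbers were 931, 10, 178 and 13. For the gene lists 343 of the values under other settings stayed the same, and 641 did so with 1 library left out. Of the 41 named genes past the threshold, total-count scaling kept 7 past it, each base counted at most once kept 9 and a cap of 10 reads per base kept 22. Of the 8 libraries in the model, the deletion extracellular ones held the fewest reads, at 57397 and 144415. In simulated libraries with these depths, 52% of genes changed 16-fold and 7% of those changed 4-fold were called between fractions of the deletion. Where no reason is given, the cause was not tested.

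Numbers of genes past the threshold moved as follows, higher first and lower second. Between fractions in wild type, where edgeR called none, total-count scaling called 1 and 1, DESeq2 16 and 35, and no low-count filter 42 and 35. A cap of 10 reads per base gave 6 and 7, each base counted at most once 11 and 11, and the joint omission of 2 libraries 43 and 24. Between fractions in the deletion, 63 and 91 became 157 and 258 without the filter, 37 and 24 with the cap, and 3 and 3 with each base counted at most once. Fitting the 2 groups alone gave 166 and 153, and the joint omission 180 and 268. Fewer were lower with total-count scaling, 11, and more with rRNA left out before scaling, 144. Between genotypes in intracellular RNA, total-count scaling gave 0 and 1, no filter 21 and 14, and the joint omission 13 and 2. The fit of 2 groups alone called 0 higher there and DESeq2 1 lower. Between genotypes in extracellular RNA, DESeq2 gave 4 and 6, no filter 25 and 18, and the joint omission 3 and 7. Counting both strands or 5 bases upstream gave 2 higher there, the 2 groups alone 0 higher, and total-count scaling 1 lower. For the interaction, total-count scaling called 1 lower and no filter 2 lower. Calls shared between wild type and the deletion, 0 in either direction by edgeR, were 1 higher with total-count scaling, 7 and 17 by DESeq2, and 17 and 20 without the filter. They were 2 and 3 with the cap, 1 lower with each base counted at most once, and 28 and 22 in the joint omission. Between the genotype comparisons the unfiltered test shared 1 higher and 1 lower.

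With the replicate block, edgeR called 72 and 103 genes between fractions in the deletion, 7 and 0 between genotypes in intracellular RNA and 1 and 0 in extracellular RNA. Deviations of libraries with the same number correlated at -0.0988 to 0.0656 across the pairs of groups, which gave no sign of pairing. Spread between libraries could hide a shared culture or day, which the labels do not settle. Under the replicate block the amino acid biosynthesis list between fractions of the deletion had a limma camera adjusted p of 0.0556. The SOS genes between genotypes in extracellular RNA turned, at 0.987. It ended no other list call, and 2 of the 41 named genes past the threshold fell short of it.

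With an estimated correlation in place of the preset one, each of the 26 list calls fell short. Between fractions in wild type, limma camera then gave 0.578 for small regulatory RNAs, heat shock genes and ribosomal proteins, and 0.348 for toxin-antitoxin RNAs, Fur genes and prophage genes. Amino acid biosynthesis genes were at 0.654 and transfer RNAs at 0.715. In the deletion it gave 0.432 for small regulatory RNAs, 0.148 for toxin-antitoxin RNAs and prophage genes, 0.465 for Fur genes, and 0.975 for amino acid biosynthesis genes and ribosomal proteins. Between genotypes in intracellular RNA the values were 0.625 for housekeeping RNAs, 0.212 for toxin-antitoxin RNAs, 0.115 for flagella genes and 0.741 for transfer RNAs. In extracellular RNA they were 0.572 for heat shock and flagella genes and 0.5 for prophage genes. For the interaction they were 0.757 for small regulatory RNAs, 0.348 for toxin-antitoxin RNAs and prophage genes, 0.822 for heat shock genes and 0.854 for transfer RNAs. The estimated correlations ran from -0.00574 for vesicle genes to 0.814 for transfer RNAs, which scales the variance of the transfer RNA list by 36.8 in place of 1.44. For prophage genes the factor came to 0.966, which limma camera raises to 1, in place of 1.09, and their calls ended as well. By its construction the test then uses the 4 residual degrees of freedom. The 2 changes were separated after the results were seen. Of the 26 calls, 2 were kept with the 4 degrees of freedom and the preset correlation, namely flagella genes (limma camera adjusted p = 0.00684) and transfer RNAs (0.0114) between intracellular genotypes. With the estimated correlation alone 10 were kept, among them each call of toxin-antitoxin RNAs and prophage genes, and flagella genes between intracellular genotypes (1.54e-06). The degrees of freedom alone thus ended 24 calls and the correlation alone 16.

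Total-count scaling turned 11 list directions, none of them of a called list. These were leader peptides in wild type at 0.829, glycolysis and TCA genes in the deletion at 0.863, and 5 lists between genotypes in intracellular RNA. The 5 were nucleoid proteins, heat shock genes, glycolysis genes and translation factors at 0.723, and outer membrane genes at 0.741. In extracellular RNA housekeeping RNAs turned at 0.928 and SOS genes at 0.982. In the interaction amino acid biosynthesis turned at 0.786 and ribosomal proteins at 0.7. It brought 6 lists past the threshold, namely flagella genes in wild type at 0.0288 and in the interaction at 0.048, and RpoS genes in the interaction at 0.0169. The others were amino acid biosynthesis between intracellular genotypes at 0.0031, and small regulatory RNAs at 0.0175 and nucleoid proteins at 0.0472 between extracellular genotypes. It left amino acid biosynthesis in the deletion at 0.053. Collapsing neighbouring members turned leader peptides in wild type at 0.811, glycolysis genes in the deletion at 0.958 and vesicle genes in the interaction at 0.985. It also turned OxyR, outer membrane, heat shock and translation factor lists between intracellular genotypes, and SOS genes between extracellular ones, each at 0.987. Flagella genes in wild type came to 0.0344. Amino acid biosynthesis came to 0.0595 in wild type and 0.336 in the deletion, where fewer members entered the test.

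Among single genes, total-count scaling turned csrC between intracellular genotypes to a log2 fold change of -0.09, and the cap turned sibC there to -0.01. The interaction value of trpT turned to 0.15 with the cap. With each base counted at most once rplQ in the deletion turned to 0.51, and the interaction values of aspTUV, proL and trpT to 0.36, 0.26 and 0.42. The joint omission turned the interaction value of arrS to 1.03. The log2 fold change of dps between intracellular genotypes passed the threshold without the filter, at -4.45, and in the joint omission, at -5.20. With 1 library left out, it ran from -5.20 to -1.65, and the dps value between fractions of wild type from -2.97 to 0.60. Between extracellular genotypes flgG ran from -4.31 to 3.98, intE from -5.71 to 3.63 and intQ from -0.40 to 2.59. Between intracellular genotypes zinT ran from -8.44 to 0.33, and between fractions of the deletion intE from -3.84 to 7.83. In wild type argX ran from -0.37 to 3.20, thrT from -0.10 to 3.80 and valW from -0.25 to 3.89. Interaction values ran from -5.78 to 0.21 for arrS, -4.34 to 5.95 for intA, -4.75 to 6.93 for intE and -0.50 to 2.51 for intQ.

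Differences in shares between the fractions, in percentage points, moved as follows. With base values capped at 10, exact p values were 0.0286 for other non-coding RNA at -2.81, protein-coding RNA at -23.2 and intergenic RNA at -8.94. Antisense RNA turned to -1.16 and 5S rRNA to 0.521. Shares outside rRNA genes turned transfer RNA to 14.8. The joint omission gave 14.9 for 16S rRNA, 15.4 for 23S, -2.77 for 5S and 27.0 for all rRNA, at an exact p of 0.1, the smallest that 3 libraries against 3 can give. The share of transfer RNA starts nearer to the 5′ end turned to -2.76 over pooled reads, -1.84 with the cap and -4.54 in the joint omission. With 1 library left out, 16S rRNA ran from 9.92 to 14.9, 23S from 12.1 to 15.5, 5S from -5.60 to -2.99 and all rRNA from 16.6 to 26.1. The rRNA kinds then fell short of the threshold, with fewer splits of libraries left to the exact permutation test. All rRNA had not passed it with all libraries either, at an exact permutation p of 0.172 adjusted over 6 classes. Transfer RNA ran from -8.01 to 5.60, antisense RNA from -0.116 to 0.354 and the share of starts nearer to the 5′ end from -1.53 to 7.16.

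Genes at 4 times the reference or more in the pull-down from LB, 3 of those with 30 reads, numbered 6 with rRNA left out, 8 among genes with 10 reads and 20 with the cap. For M9, 4 became 2, 8 and 2. Without 1 of the reference libraries the number for LB was 4 or 11. The correlation of LB enrichment with the genotype difference passed its permutation test by Pearson at 0.631 and over genes with at least 10 pull-down reads at 0.126. For M9 it no longer passed over genes with a mean of 30 reads, at 0.244.

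With 1 library left out, genes called between fractions numbered 0 to 33 higher and 0 to 6 lower in wild type, and 0 to 128 higher and 0 to 173 lower in the deletion. Between genotypes they numbered 0 to 7 higher and 0 to 3 lower in intracellular RNA, and 0 to 1 higher in extracellular RNA. For the interaction 0 to 1 were lower. Shared calls of wild type and the deletion numbered 0 to 22 higher and 0 to 1 lower.

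List values with 1 library left out are limma camera adjusted p, lowest to highest, for each list that crossed the threshold or turned. For fractions in wild type, small regulatory RNAs gave 0.00161 to 0.204, housekeeping RNAs 0.0354 to 0.907 and leader peptides 0.187 to 0.76. RpoS genes gave 0.0576 to 0.949, heat shock genes 1.76e-06 to 0.457 and SOS genes 0.557 to 0.949. Flagella genes gave 0.000152 to 0.861, amino acid biosynthesis 4.53e-08 to 0.567 and glycolysis and TCA genes 0.00416 to 0.901. Translation factors gave 0.0449 to 0.232, RNA degradation genes 0.283 to 0.879, prophage genes 0.0172 to 0.201 and transfer RNAs 1.48e-14 to 0.39. For fractions in the deletion, RpoS genes gave 0.0129 to 0.852, OxyR and SoxRS genes 0.419 to 0.858 and Fur genes 0.00067 to 0.133. Nucleoid proteins gave 0.43 to 0.874, SOS genes 0.809 to 0.974 and amino acid biosynthesis 0.00156 to 0.157. Glycolysis and TCA genes gave 0.419 to 0.961, vesicle genes 0.43 to 0.858 and ribosomal proteins 0.00183 to 0.43.

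Between intracellular genotypes, small regulatory RNAs gave 0.0292 to 0.422, housekeeping RNAs 8.25e-06 to 0.0946 and toxin-antitoxin RNAs 0.000471 to 0.065. Leader peptides gave 0.576 to 0.997, RpoS genes 0.000566 to 0.901 and OxyR and SoxRS genes 0.0752 to 0.997. Fur genes gave 0.252 to 0.997, nucleoid proteins 0.501 to 0.997 and outer membrane genes 0.787 to 0.997. Heat shock genes gave 0.422 to 0.964, SOS genes 0.299 to 0.997 and amino acid biosynthesis 1.32e-05 to 0.932. Glycolysis and TCA genes gave 0.0262 to 0.916, translation factors 0.576 to 0.997 and prophage genes 0.867 to 0.997. Ribosomal proteins gave 0.0203 to 0.901 and transfer RNAs 2.21e-30 to 0.0942. Between extracellular genotypes, small regulatory RNAs gave 0.0443 to 0.298, housekeeping RNAs 0.0588 to 0.847 and toxin-antitoxin RNAs 0.00839 to 0.298. RpoS genes gave 0.0307 to 0.95, OxyR and SoxRS genes 0.243 to 0.818 and nucleoid proteins 0.0384 to 0.585. SOS genes gave 0.606 to 0.792, translation factors 0.0179 to 0.0632 and vesicle genes 0.1 to 0.891. Prophage genes gave 0.00302 to 0.089, ribosomal proteins 0.0242 to 0.79 and transfer RNAs 1.91e-07 to 0.79.

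For the interaction, small regulatory RNAs gave 0.00216 to 0.0796, housekeeping RNAs 0.000451 to 0.41 and toxin-antitoxin RNAs 0.000182 to 0.0666. RpoS genes gave 0.00104 to 0.63, OxyR and SoxRS genes 0.16 to 0.937 and nucleoid proteins 0.0413 to 0.606. SOS genes gave 0.691 to 0.937, flagella genes 4.92e-06 to 0.424 and amino acid biosynthesis 0.0276 to 0.937. Glycolysis and TCA genes gave 0.00998 to 0.749, translation factors 0.0156 to 0.0825 and vesicle genes 0.25 to 0.992. Prophage genes gave 0.00696 to 0.123, ribosomal proteins 0.0775 to 0.937 and transfer RNAs 7.65e-18 to 0.535.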

Other observations

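All tests of explanations in this part were chosen after the results were seen. Reads of the RNA fimR2 and of the site next to it varied widely between libraries. The RNA took 8.36% and 17.0% of gene reads in wild-type intracellular libraries, 7.56% and 9.88% in deletion intracellular ones, 0.223% and 0.194% in deletion extracellular ones, and 1.40% and 28.6% in wild-type extracellular ones. Between fimA, the major pilus subunit gene, and fimR2, position 4543673 of the top strand held 83.9% of the interval's reads. That interval held 165000 RPM in wild-type extracellular library 2 and 12400 in library 1, and 2610 and 1080 in the deletion's extracellular libraries.

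Reads on the strand opposite to genes were also uneven, over 1238 genes with a clear strand, a set chosen after the data were seen. They were 12.9% and 17.0% of these genes' reads in deletion extracellular RNA and 10.3% and 3.76% in wild-type extracellular RNA. In intracellular libraries they were 4.30% to 5.61%, and in the pull-downs 1.37% and 3.58%. Fractional values, from reads with several matches, held 59.7% and 55.8% of opposite-strand positions in deletion extracellular, 52.4% and 8.02% in wild-type extracellular and 7.0% to 26.2% in intracellular libraries. Over whole-number positions alone the shares were 9.72% and 14.4%, 8.53% and 3.73%, and 4.11% to 5.34%. Over the 54 genes with at least 10 reads in the M9 pull-down, a setting also chosen afterwards, enrichment correlated with the extracellular difference between genotypes at a Spearman rho of 0.325 (mean of 0.0653 under permutation within expression deciles, permutation p = 0.0053). For LB the value was 0.126 over 54 genes (mean of -0.119, permutation p = 0.009). Genes are not independent replicates, and with a mean of at least 30 reads neither medium passed.

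The 63 genes higher outside the deletion's cells had few reads, a median of 5.4 per library on average against 114 for the 91 lower ones. A lower depth outside could produce such calls, but with each library thinned to the smallest, at 53850 reads, a median of 3 of the 63 were still tested and 2.5 still called, so depth stays open. Among the higher genes, a median of 51.6% of deletion extracellular reads began at the commonest base, with over 50% in 34 of 62 genes. Among the lower genes this was 39.6% of deletion intracellular reads, with over 50% in 35 of 91. Such shares run high where reads are few. Stacks of amplified reads at single bases could also produce the 63 calls. With each base counted at most once, 51 of the 63 stayed higher at an unadjusted p under 0.05 and 3 by edgeR adjusted p, with the median log2 fold change going from 4.94 (SD 1.95) to 3.42 (SD 1.83), so this stays open too, since counting a base once lowers the counts and ended most calls. With rRNA left out before scaling, 59 of the 63 were still called, at a median log2 fold change of 4.71 (SD 1.94). This moved the median of all genes only from -0.44 to -0.64, too little to turn genes at a median of 4.94. That test took the place of total counts, which kept all 63 positive and called 34 but raised all genes only to -0.03. The direction thus held under these scalings, while scaling as a cause of the calls cannot be decided.

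Wild-type extracellular library 2 lay nearer to intracellular libraries, with correlations of 0.77, 0.82, 0.80 and 0.78, than to the other extracellular ones, at 0.72, 0.49 and 0.50. RNA of lysed or carried-over cells could give this. In this library fimR2 took 28.6% of gene reads, above the 7.56% to 17.0% of intracellular libraries. That is 1 RNA in 1 library, and its share also varied between intracellular libraries, so carry-over stays open. An intracellular library under a wrong label is argued against by 16S and 23S rRNA, at 16.4% of gene reads here and at most 4.83% in intracellular libraries. No biological explanation was tested.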
